A study of Mus musculus with 9 samples.

How the data were processed

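RNA was measured by sequencing in B16F10 cells, a mouse melanoma line, after 6 h in medium alone, in medium with interferon gamma (IFNγ) at 50 ng/mL, or in medium with IFNγ at 50 ng/mL and FK866 at 50 nM. FK866 inhibits NAMPT, the rate-limiting enzyme of the NAD salvage pathway. Each of the 3 groups has 3 libraries, whose titles carry the word Control with the numbers 3, 4 and 5, also where IFNγ was given. What Control 3, 4 and 5 stand for is not stated. The labels do not say whether libraries of a group come from separate cultures, so p-values measure only the spread between these libraries. No group received FK866 alone, so an effect of FK866 without IFNγ, or an interaction of both, was not analysed here.

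The deposited table holds raw read counts per Ensembl gene, 1 column per library, which the values show as whole numbers with a different total in each library. It was treated as bulk RNA sequencing because it holds no values per cell, although the series text names a droplet platform used for single cells. STAR 2.7.6a, cutadapt 1.16, featureCounts 1.6.3 and DESeq2 1.30.1 are named with the builds GRCm38 and mm10, per the submitters' processing notes, which in the form used here give no role or order. The strand setting, the annotation release and any removal of duplicates are not given in the sources used here. Without a stated strand, reads of a gene and an overlapping antisense gene cannot be told apart. Genes with near-identical copies are uncertain, because counting could split or drop their reads. Among the genes named here this concerns the guanylate-binding proteins, Tgtp1 with Tgtp2, Iigp1, the class I genes of the H2 region, Ifit3, and pseudogenes. The labels state polyA RNA, yet 2.94% to 4.48% of the counts of a library fell on Rn7sk, Rpph1 and an rRNA gene.

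The table has 55487 genes, of which 55141 were given a symbol from the gene name table and the same number matched the GENCODE M21 annotation of GRCm38, the source of the coordinates printed here. Zero counts in every library were found for 28707 genes. Library totals ran from 15317003 to 18466972 counts. Replicate pairs within a group differed by far more than sampling noise (chi-square per degree of freedom from 21.59 to 37.22), so no library was merged with another. Counting intervals and floors cover counting error only.

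Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test), with all 9 libraries in 1 fit of group means, and p-values were adjusted by the Benjamini-Hochberg method over the 15237 genes kept, which hold 99.89% of the counts. A gene was called at an adjusted p below 0.05, and calls were counted again with at least a 2-fold change. Levels are TMM-normalised CPM as mean ± SD with n = 3. Standard errors of log2 fold changes were derived from the F statistic. Where every media library had 0 counts, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts, the ratio is given with its 95% counting interval. The 3 comparisons were IFNγ with media, IFNγ plus FK866 with IFNγ, and IFNγ plus FK866 with media.

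The number in the titles pairs the libraries. This comes from the titles together with the data, where deviations from the group means correlated by 0.555 to 0.728 over the 9 pairs of libraries with the same number and by -0.477 to -0.112 over the 18 pairs with different numbers. A fit with the number as a block, planned as an alternative, lowered the median standard error of the IFNγ comparison with media from 0.213 to 0.107. The fit without the block leaves the difference between numbers in its error, so a gene it does not call may still differ within the pairs. The value with the block is printed beside a result where it changes a call or moves a count by more than 1.5-fold.

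Gene lists (26, fixed before the data were examined) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Members that rose or fell were counted over all genes and again adjusted over the list alone. The named genes follow a rule fixed at the same stage: Nampt, Irf1, Cd274, Cxcl10 and B2m everywhere, with 1 other gene that is not reported here; per comparison the 6 largest rises and 6 largest falls among called genes with a mean CPM of at least 5 and no overlap between groups, leaving out names of predicted genes, Riken clones and pseudogenes; the 3 members with the smallest p of each list described; and, among genes induced by IFNγ at least 2-fold, the 6 with the smallest p for a fall and the 6 for a rise with FK866, at a mean CPM of at least 5. Other members of a list may be named with their values. Gm28661, Gm24497, CT010467.1, Lars2, Rn7sk and Rpph1 were chosen after their values were seen, as were the genes that differ between numbers.

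Because IFNγ libraries enter 2 of the comparisons with opposite sign, and media libraries enter 2 as well, groups without an FK866 effect, and groups without any effect, were simulated 20 times. The scripts were tested on simulated counts with 200 changed genes, 50 per fold size. For the comparison of IFNγ plus FK866 with IFNγ, 0%, 6%, 34% and 70% of changes of 1.25-fold, 1.5-fold, 2-fold and 4-fold were recovered over the 14845 genes of that test, and 40%, 68%, 82% and 98% with the block, which made 5 false calls. Alternatives were other size factors, library totals alone, other filters on low counts, DESeq2 1.42.0, limma-voom, only the 2 groups compared, the block, and leaving out each of the 9 libraries in turn; for the induced genes also another baseline library and another definition; for the lists the other set tests.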

Results

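The data set compares 3 groups of B16F10 mouse melanoma cells, 3 libraries each, by RNA sequencing, treated as bulk, after 6 h. Total counts in the libraries numbered 3, 4 and 5 were 15470783, 17760231 and 17416251 in media, 15564222, 16085311 and 17730595 with IFNγ, and 18126534, 18466972 and 15317003 with IFNγ plus FK866. Over the 500 most variable genes, the leading principal component (56.1% of the variance) separated media from both IFNγ groups, and the next (28.9%) separated libraries with number 3 from those with numbers 4 and 5. The IFNγ and IFNγ plus FK866 libraries of the same number lay close together on both.

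**Figure D1:**
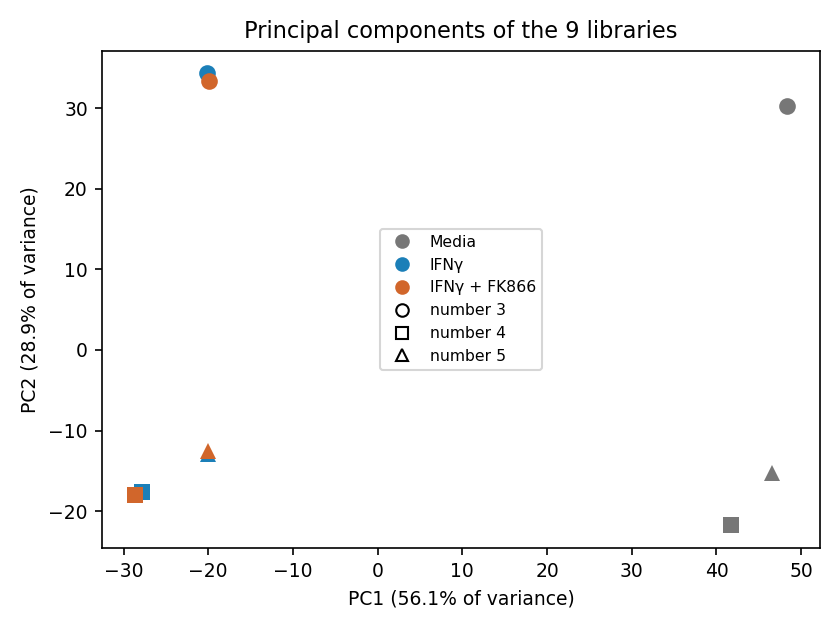
Principal components of the 9 libraries, computed from log2 CPM of the 500 most variable genes; the x axis is the component with 56.1% of the variance and the y axis the one with 28.9%. Colours mark the groups and shapes the number in the titles; the media libraries lie at 41.75 to 48.34 on the x axis and all others at -28.64 to -19.9.

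The comparison of IFNγ with media asks how the melanoma cells respond to the cytokine. Irf1, a transcription factor of the interferon response, rose from 17.3 ± 3.31 to 787 ± 34.2 CPM (SD, n = 3), a log2 fold change of 5.51 with a standard error of 0.16. Cd274, which encodes the checkpoint ligand PD-L1, rose from 7.97 ± 2.64 to 262 ± 39.0 CPM. Nampt, the target of FK866, rose 2.79-fold from 192 ± 33.4 to 538 ± 47.1 CPM. Mitf, the master regulator of the melanocyte lineage, fell from 807 ± 68.4 to 335 ± 60.5 CPM.

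The edgeR adjusted p-values were 3.97e-08 for Irf1, 3.71e-06 for Cd274, 5.04e-04 for Nampt and 7.73e-04 for Mitf. Cxcl10, a chemokine that attracts T cells, rose from 40.5 ± 33.6 to 1094 ± 583 CPM, with a log2 fold change of 4.75, a standard error of 0.69 and an adjusted p of 0.00377. B2m, the light chain of MHC class I, had 261 ± 15.4 CPM in media and 550 ± 140 CPM with IFNγ, and its adjusted p of 0.072 did not pass. With the replicate block B2m was called, with a log2 fold change of 1.01 and an adjusted p of 2.06e-05, as it was with DESeq2 (0.00277), with only these 2 groups in the fit (0.0257) and without the filter on low counts (0.00856). It was also called without IFNγ library 5 (log2 fold change 1.27, adjusted p = 0.0388) and without IFNγ plus FK866 library 5 (1.07, adjusted p = 0.0131). In GRCm38, these 6 genes are annotated as protein-coding. Irf1 lies on chromosome 11 from 53770014 to 53778374 and Cd274 on chromosome 19 from 29367455 to 29388095. Nampt lies on chromosome 12 from 32819545 to 32853349 and Cxcl10 on chromosome 5 from 92346638 to 92348889. B2m lies on chromosome 2 from 122147686 to 122153083 and Mitf on chromosome 6 from 97807052 to 98021349.

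The largest rises were in genes with no or almost no counts in media. Iigp1, an immunity-related GTPase, was at least 11000-fold higher with IFNγ, Tgtp1, of the same family, at least 4310-fold, the apolipoprotein L gene Apol6 at least 785-fold. The transcription factor Batf2 was at least 784-fold higher, and Ciita, the transactivator of MHC class II genes, at least 637-fold. Tgtp2 had 1 count over the media group, which gives a ratio of 17600 with a 95% counting interval of 3150 to 694000. Reads of Tgtp1 and Tgtp2 may be shared between these near-identical genes. The largest falls were in Rab3a (log2 fold change -2.02, standard error 0.28), Gjb2 (-1.46, 0.28), Rapgef3 (-1.27, 0.12), Mitf (-1.27, 0.15), Zfp469 (-1.26, 0.26; annotated as a lincRNA in this release) and Stum, from 23.8 ± 6.98 to 9.99 ± 1.86 CPM. The fits that leave out 1 library are without the block, so each breaks a pair. The block with all libraries kept every call of the fit without it. The call of Gjb2 was lost without media 3 or 5 or IFNγ 3 or 4 (adjusted p = 0.0562, 0.0836, 0.0728 and 0.0911). That of Zfp469 was lost without media 3, 4 or 5 or IFNγ 4 or 5 (0.108, 0.0569, 0.0823, 0.143 and 0.109), and that of Stum without media 4 or 5 or IFNγ 3 or 5 (0.0789, 0.0518, 0.0781 and 0.0824).

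**Figure D2:**
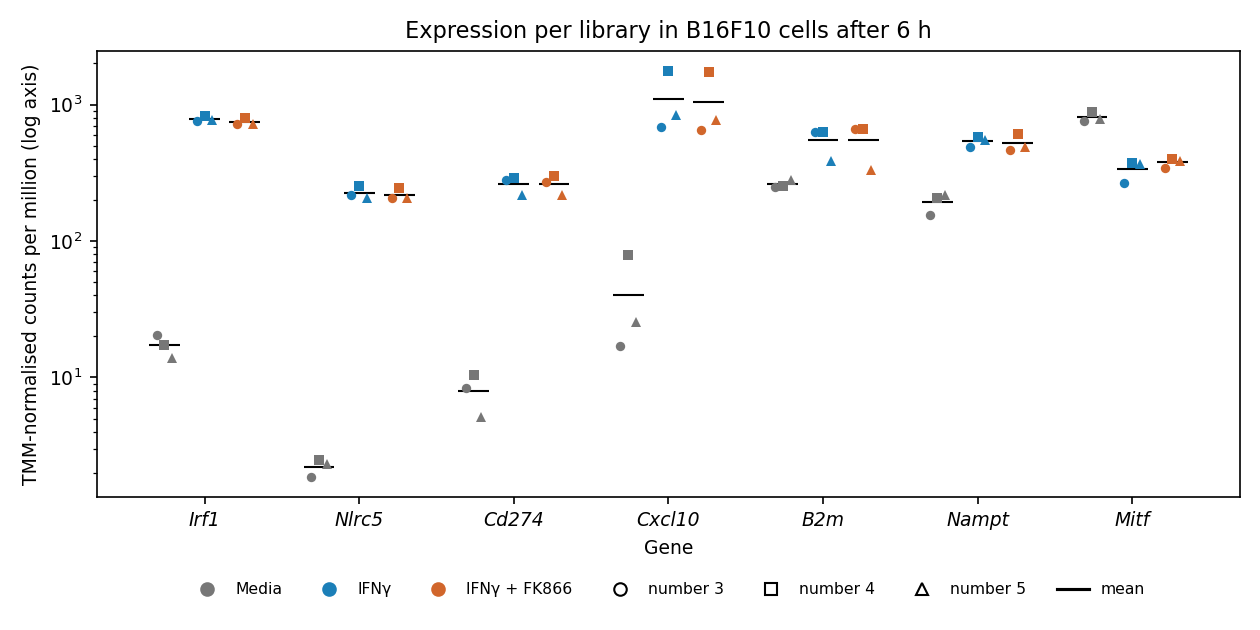
TMM-normalised CPM (log axis) of 7 genes in each of the 9 libraries; colours mark the groups, shapes the number in the titles and horizontal lines the group means. In the fit without the block, Irf1, Nlrc5, Cd274, Cxcl10 and Nampt passed the threshold as higher in both IFNγ groups against media. Mitf passed as lower in both, and B2m passed in neither. With the block B2m passed in both. None of the 7 passed between IFNγ and IFNγ plus FK866.

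Genes of the interferon response rose as groups. Of the IFN-inducible GTPases, which act against intracellular pathogens, 18 of 19 measured members rose (18 adjusted over the list alone; camera adjusted p = 4.59e-06 with an estimated correlation). Igtp went from 0.372 ± 0.053 to 1106 ± 88.1 CPM, and Gbp6, with 1 count in media, had a ratio of 5360 with a counting interval of 962 to 212000. Of the JAK-STAT and IRF regulators, 13 of 18 rose (15 adjusted over the list alone; adjusted p = 2.84e-04 with an estimated correlation), among them the feedback inhibitor Socs1 with a log2 fold change of 6.44 and a standard error of 0.14. With the block 15 rose and 1 fell. Of the type I IFN and antiviral genes, 29 of 33 rose (32 adjusted over the list alone; adjusted p = 0.00278 with an estimated correlation). Parp14 and Dtx3l, of ADP-ribosylation and ubiquitin signalling, had log2 fold changes of 6.81 (standard error 0.25) and 4.64 (0.19), and Ifit3, whose reads may be shared with a copy, 4.90 (0.20).

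Antigen presentation genes followed. Of the MHC class I presentation list, 12 of 18 measured members rose (17 adjusted over the list alone; adjusted p = 4.72e-04 with an estimated correlation). These included the transactivator Nlrc5, from 2.23 ± 0.304 to 225 ± 25.7 CPM, and the immunoproteasome subunit Psmb10, from 5.31 ± 0.527 to 55.7 ± 3.23 CPM. Psmb9, with 2 counts in media, had a ratio of 310 with a counting interval of 85.9 to 2560. Of the MHC class II list only 3 of 11 members were measured, and 1 of these rose, Ciita (1 adjusted over the list alone; adjusted p = 0.0444 with an estimated correlation and 0.0796 with an estimated correlation and the block). The class II invariant chain Cd74 (0.92 ± 0.785 CPM with IFNγ) and H2-DMa (3.23 ± 0.287 CPM) had log2 fold changes of 0.74 and -0.18 and were not called.

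Of the checkpoint and costimulatory ligands, 3 of 8 rose (3 adjusted over the list alone, 6 of 8 with the block; adjusted p = 0.00278 with an estimated correlation). Beside Cd274 these were the receptor genes Tnfrsf14 (log2 fold change 4.18, standard error 0.29) and Fas (3.91, 0.85). The call of Fas was lost with limma-voom (adjusted p = 0.0956), with library totals alone (0.0508) and without media 3, 4 or 5 or IFNγ 3 or 4 (0.12, 0.0866, 0.0914, 0.0753 and 0.141). Of the chemokines and cytokines, 5 of 10 rose (7 adjusted over the list alone), with Il18bp, an IL-18 antagonist, at 1.10 (0.17) and Cx3cl1 at 2.93 (0.51). That list's adjusted p was 0.0831 with an estimated correlation and 0.00545 with an estimated correlation and the block. The call of Cx3cl1 was lost with limma-voom (adjusted p = 0.0508) and without media library 5 (0.0523).

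Genes of NAD metabolism moved in part. In the NAD biosynthesis list 1 of 15 measured members rose, Nampt (1 adjusted over the list alone, 2 with the block; camera adjusted p = 0.814, direction up, with a list median of -0.15 and a mean of 0.04). Nnmt, which methylates nicotinamide, had 3.80 ± 2.46 CPM in media and 12.1 ± 4.35 CPM with IFNγ and an adjusted p of 0.181, and was called with the block at 2.28e-07, with DESeq2 at 0.021 and without the filter on low counts at 0.044. Haao, an enzyme of the kynurenine route to NAD, had a log2 fold change of -1.04 with an adjusted p of 0.621. Of the NAD-consuming enzymes, 5 of 20 rose (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0713 with an estimated correlation and 0.0308 with an estimated correlation and the block). The 3 members with the smallest p were the ADP-ribosyltransferases Parp10 at 10.9-fold, Parp12 at a log2 fold change of 3.09 (standard error 0.30) and Parp11 at 1.40 (0.18).

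In the melanocyte lineage list 1 of 16 members fell, Mitf (1 adjusted over the list alone, 8 with the block, where 1 also rose; camera adjusted p = 0.0232, and adjusted p = 0.301 with an estimated correlation). Rab27a and Sox10 had log2 fold changes of -0.38 and -0.31 and were called only with the block (adjusted p = 1.31e-04 and 0.00175). In the immediate early genes 2 of 14 rose (2 rose and 2 fell adjusted over the list alone; 6 rose and 5 fell with the block; camera adjusted p = 0.491, direction up, median -0.03, mean 0.11), Zfp36 at 2.19 (standard error 0.25), an mRNA decay factor, and Jun at 1.44 (0.25); Klf4 had -1.08 and was called only with the block (adjusted p = 0.00491). In the ATF4 and amino acid stress list 2 of 25 rose (2 adjusted over the list alone; 5 rose and 3 fell with the block; camera adjusted p = 0.73), Atf3 at 5.67-fold and Cebpb at a log2 fold change of 1.01 (0.23), while Ddit3 had -0.41 and was called only with the block (adjusted p = 0.0449). The call of Jun was lost without media 4 or 5 (adjusted p = 0.0622 and 0.0644) and that of Atf3 without media 5 (0.0586). That of Cebpb was lost without media 3, 4 or 5, IFNγ 3 or 5 or IFNγ plus FK866 5 (0.0736, 0.207, 0.167, 0.163, 0.151 and 0.0786), with DESeq2-style size factors (0.0513) and with limma-voom (0.0815).

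In the NRF2 and redox list 1 of 16 rose, Osgin1, at 1.64 with a standard error of 0.21 (2 adjusted over the list alone and 2 with the block; camera adjusted p = 0.453). Gclm and Txnrd1, of glutathione and thioredoxin metabolism, had 1.03 and 0.19, and Gclm was called with the block (adjusted p = 2.13e-10), with DESeq2 (0.0078) and without the filter on low counts (0.0147). In the hypoxia list Ero1l rose 2.29-fold and Ndrg1 fell by 1.23 on the log2 scale (0.15), 1 up and 1 down of 16 (the same adjusted over the list alone; 2 up and 6 down with the block; camera adjusted p = 0.289), and Kdm3a had 0.51 and was called only with the block (adjusted p = 5.62e-06). The call of Ero1l was lost without media 4 or 5, IFNγ 3 or 4 or IFNγ plus FK866 4 (adjusted p = 0.152, 0.143, 0.0915, 0.0615 and 0.056). Of the NF-kB targets 0 of 13 were called (4 rose adjusted over the list alone and 6 with the block; camera adjusted p = 0.0565, 0.0155 with the block, and 0.126 with the block and an estimated correlation). Tnfaip2 had 1.03, Vcam1 2.72 and Nfkbiz 0.91, called with the block at adjusted p = 6.07e-09, 0.00801 and 4.99e-07. Tnfaip2 and Nfkbiz were also called with DESeq2 (0.00742 and 0.0355), Tnfaip2 without the filter on low counts (0.017), and Vcam1, which had 6 counts over the media group, without IFNγ 5 (0.0287). No member was called in the lists of glycolysis (21 measured), nuclear OXPHOS subunits (36), mitochondrially encoded genes (13), ER chaperones (16), DNA replication (20), mitosis (20), p53 targets (17), cholesterol biosynthesis (20), MYC and ribosome biogenesis (18) and leukocyte markers (2), adjusted over the list alone likewise 0, with camera adjusted p-values from 0.393 to 0.994. Median, mean and test differed in sign for ER chaperones, mitosis, p53 targets and MYC and ribosome biogenesis, none past the threshold. With the block 1 rose and 3 fell in glycolysis, 3 rose and 1 fell in p53 targets, 3 fell in cholesterol biosynthesis, and at most 1 rose or fell in each of the others.

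Markers of other cell types stayed low. Scaled by library totals, leukocyte markers reached at most 11.7 CPM, for Cd68, and fibroblast, endothelial and keratinocyte markers at most 7.58 CPM, for Pdgfra. Of the latter list 2 of 12 members were measured and 1 fell, the collagen gene Col1a2, from 5.45 ± 1.24 to 1.68 ± 0.328 CPM (adjusted p = 0.00952; 1 adjusted over the list alone; camera adjusted p = 0.0785).

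In total 427 genes were higher and 76 lower with IFNγ than in media (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05; 325 and 24 by at least 2-fold). With the replicate block 1237 were higher and 936 lower, and these included all 503 calls of the fit without it. The number of lower genes was 180 with DESeq2, and 26 without IFNγ library 3, 26 without IFNγ library 4, 43 without IFNγ library 5, 39 without media library 3, 27 without media library 4 and 26 without media library 5.

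The comparison of IFNγ plus FK866 with IFNγ asks whether FK866, an inhibitor of NAMPT, alters the response. Levels of the response genes were close in both groups. Irf1 had 747 ± 42.4 CPM with FK866 and 787 ± 34.2 without (n = 3 each), Cd274 263 ± 42.5 and 262 ± 39.0, and Cxcl10 1053 ± 593 and 1094 ± 583. Nampt itself had 522 ± 79.9 and 538 ± 47.1 CPM, a log2 fold change of -0.04 with a standard error of 0.16. With the block, which removes the spread between numbers, the 95% intervals of the log2 fold change were -0.24 to 0.08 for Irf1 and -0.14 to 0.15 for Cd274. They were -0.28 to 0.14 for Cxcl10, -0.31 to 0.27 for B2m and -0.20 to 0.11 for Nampt.

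Within the pairs of libraries with numbers 3, 4 and 5, the differences in log2 CPM were -0.083, -0.054 and -0.092 for Irf1 and -0.07, -0.023 and -0.118 for Cxcl10, and of mixed sign for Nampt (-0.062, 0.085 and -0.175) and Cd274 (-0.035, 0.052 and -0.002). In the fit without the block, which does not keep the pairs, some signs changed when 1 library was left out. Nampt had 0.01 without IFNγ 4 and 0.03 without IFNγ plus FK866 3. Cd274 had -0.11 without IFNγ 5, -0.02 without IFNγ plus FK866 3 and -0.10 without IFNγ plus FK866 4. Cxcl10 had 0.47 without IFNγ 4, 0.20 without IFNγ plus FK866 3 and 0.12 without IFNγ plus FK866 5; its level differed between numbers (682.32, 1760.87 and 839.76 CPM with IFNγ in 3, 4 and 5), which shifts this fit when a pair is broken.

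No gene was called between IFNγ plus FK866 and IFNγ (edgeR, 15237 genes), and 88 had an unadjusted p below 0.05. Chance alone would give 762 in a fit that accounts for the pairs. This fit leaves the spread between numbers in its error (median standard error 0.212, and 0.106 with the block). The count of 88 against 762 therefore does not measure how close the groups are. DESeq2 and limma-voom, also without the block, called 0, with 61 and 85 genes at an unadjusted p below 0.05. With the replicate block 3 genes were called, all non-coding, and 573 had an unadjusted p below 0.05. They are Gm28661, an unprocessed pseudogene on chromosome 1 from 24614885 to 24615565 (log2 fold change 0.74, adjusted p = 0.00281), Gm24497, an snRNA gene on chromosome 1 from 72244213 to 72244403 (1.90, 0.0311), and CT010467.1, an rRNA gene on chromosome 17 from 39846353 to 39848827 (-0.47, 0.0311). Counts on a pseudogene can hold reads of its parent gene, and these 3 were chosen after their values were seen. A check for carry-over of rRNA as the source of the CT010467.1 counts was not run, since the genes it was to use are not among the 15237 genes tested. That source stays open. CT010467.1 held 1.70%, 2.09% and 1.56% of the counts on average in media, with IFNγ and with IFNγ plus FK866. With the block, Lars2, also chosen after its values were seen, was called with IFNγ against media (0.38, adjusted p = 0.00305). It was not called with FK866 against IFNγ (-0.29, 0.987). Rn7sk (0.09 and -0.1) and Rpph1 (0.12 and -0.09) were called in neither comparison. Gm24497 was higher with FK866 in numbers 4 (19.2 against 5.30 CPM) and 5 (28.2 against 3.67 CPM) and lower with it in number 3 (2.29 CPM with FK866). With the block in DESeq2, Gm28661 was the only call. In the comparison of IFNγ with media, the block called these 3 genes with log2 fold changes of -0.41, -1.98 and 0.34 (adjusted p = 0.0041, 5.63e-05 and 0.00381). The IFNγ libraries enter both comparisons with opposite sign, so opposite values arise without an effect: across genes the log2 fold changes of both correlated by -0.508 in simulations without any effect and by -0.139 in those without an FK866 effect. Between IFNγ plus FK866 and media, Gm28661 was called with the block (0.33, 0.0158).

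Of the 325 genes induced at least 2-fold by IFNγ, 172 (52.9%) had a lower value with FK866, where simulations without an FK866 effect gave 53.5% (47.6% to 59.0%). The simulations drew IFNγ plus FK866 from the IFNγ means, so their range may not cover genes that move together between libraries. The median log2 fold change of the 325 genes was -0.006, and the medians within the pairs of libraries with the same number were -0.012, 0.012 and -0.034. None was called, with or without the block. The 95% interval excluded a fall of 1.5-fold for 273 of the 325 genes with the block and for 161 without it, and a rise of 1.5-fold for 268 with the block. The 6 induced genes with the smallest p for a fall were Osgin1 (log2 fold change -0.20), Maff (-0.28), Cdc42ep2 (-0.25), Pqlc1 (-0.20), Psmb10 (-0.13) and Kazn (-0.15). Those for a rise were Gbp4 (0.26), Il18bp (0.21), Gm47017 (0.38), Parp8 (0.19), Gm17435 (0.24) and Zfp160 (0.10), each with an adjusted p of 1. In the fit without the block, where leaving out 1 library breaks a pair, the share of lower genes was 77.3% without IFNγ library 5, 71% without IFNγ plus FK866 library 4, 33.3% without IFNγ library 4 and 30.9% without IFNγ plus FK866 library 5.

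**Figure D3:**
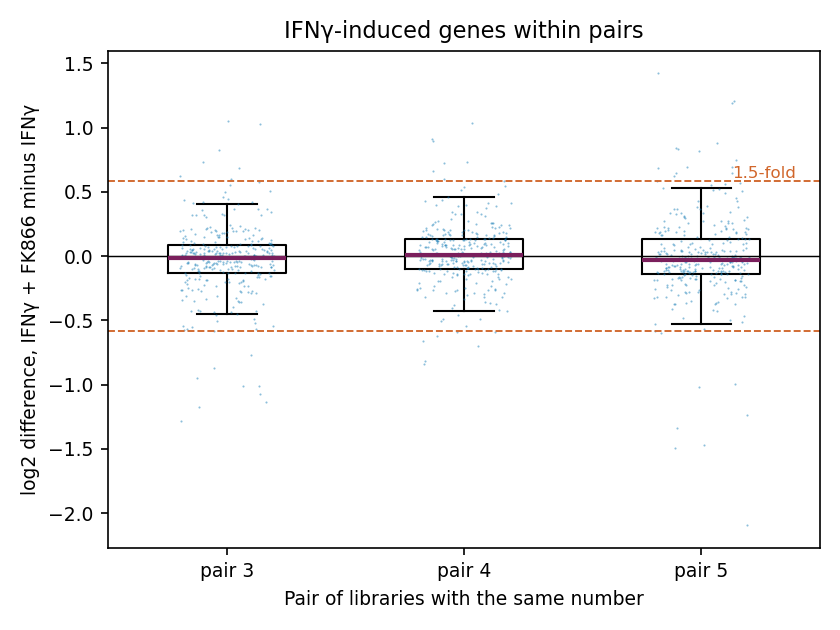
Difference in log2 CPM between the IFNγ plus FK866 and the IFNγ library of each number (y axis) for the 325 genes induced at least 2-fold by IFNγ; points are genes, boxes span the quartiles with the median, whiskers reach 1.5 times the box, and dashed lines mark a change of 1.5-fold. The medians of the 3 pairs are -0.012, 0.012 and -0.034.

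Among the fixed lists, 3 passed camera at the preset correlation with 0 members called, all towards lower values. The immediate early genes had an adjusted p of 0.0126 (14 measured; adjusted p = 0.188 with an estimated correlation), with Fosb at -0.72 (standard error 0.28), Klf2 at -0.60 (0.40) and Ier2 at -0.20 (0.17). Adjusted over the list alone 0 of these were called; with the block 0 fell over all genes and 4 adjusted over the list alone. The NRF2 and redox list had an adjusted p of 0.0191 (16 measured; adjusted p = 0.188 with an estimated correlation), with Gsr at -0.12 (0.10), Osgin1 at -0.20 (0.20) and Taldo1 at -0.16 (0.18). The nuclear OXPHOS subunits had an adjusted p of 0.0191 (36 measured; adjusted p = 0.984 with an estimated correlation), with Ndufa1 at -0.28 (0.30), Uqcrfs1 at -0.16 (0.18) and Ndufa9 at -0.12 (0.15). With the block 7 lists passed, the others being the IFN-inducible GTPases towards higher values (adjusted p = 0.00232) and p53 targets (0.00143), ATF4 and amino acid stress (0.0269) and glycolysis (0.042) towards lower values; with the block and an estimated correlation 0 passed.

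The remaining lists had no called member and no list call without the block (camera adjusted p from 0.138 to 0.972), and 0 members passed adjusted over the list alone. In the IFN-inducible GTPases Gbp9 had 0.57 (standard error 0.35), Gbp4 0.26 (0.20) and Gbp11 0.49 (0.50). In NAD biosynthesis (15 measured, 0 called, also adjusted over the list alone, where 1 fell with the block), Nmrk2 had -1.10 (0.50) at under 1 CPM, Nadk -0.21 (0.11) and Afmid -0.27 (0.21). In the NAD-consuming enzymes (20 measured, 0 called, also adjusted over the list alone) Parp8 had 0.19 (0.16), Tnks2 -0.08 (0.09) and Sirt7 -0.13 (0.16). In the ATF4 and amino acid stress list Ddit3 had 0.20 (0.17), Cth -0.36 (0.32) and Cebpb 0.16 (0.23), which was -0.06 without IFNγ plus FK866 3. Mitf had 377 ± 30.9 CPM with FK866 and 335 ± 60.5 CPM without, a log2 fold change of 0.17 with a standard error of 0.14.

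The comparison of IFNγ plus FK866 with media asks how the cells respond to the cytokine in the presence of FK866. Irf1 rose by 5.43 on the log2 scale (standard error 0.16, adjusted p = 4.39e-08), Cd274 by 5.04 (0.27, 3.67e-06), Cxcl10 by 4.70 (0.69, 0.00392) and Nampt by 1.44 (0.16, 6.14e-04). Iigp1 was at least 11700-fold higher, Tgtp1 at least 4460-fold, Apol6 at least 808-fold, Batf2 at least 798-fold, Gbp4 at least 720-fold and Ciita at least 649-fold. Tgtp2 had a ratio of 18500 with a counting interval of 3330 to 732000. The largest falls were Rapgef3 (-1.51, standard error 0.12), Gjb2 (-1.48, 0.28), Rab3a (-1.35, 0.27), Zfp469 (-1.28, 0.26), Stum (-1.27, 0.24) and Ndrg1, from 157 ± 7.08 to 66.2 ± 11.7 CPM, and Mitf fell by 1.10 (0.15). B2m, at 549 ± 190 CPM, had an adjusted p of 0.0727 and was called with the block (log2 fold change 0.99, adjusted p = 2.69e-05), without IFNγ plus FK866 5 (1.33, 0.00656), with DESeq2 (0.00273) and without the filter on low counts (0.00851).

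Among the lists, 13 of 18 JAK-STAT and IRF regulators rose, 18 of 19 IFN-inducible GTPases, and 12 of 18 MHC class I genes with Nlrc5 at 6.61. So did 1 of 3 class II genes, 3 of 8 checkpoint ligands, 5 of 10 chemokines, 29 of 33 antiviral genes with Parp14 at 6.86, 1 of 15 NAD biosynthesis genes and 5 of 20 NAD-consuming enzymes. Adjusted over the list alone these counts were 15 up and 1 down, 18, 16, 1, 3, 7, 32, 2 up and 1 down, and 7 up and 1 down. Lists whose call was lost were the chemokines (adjusted p = 0.0878 with an estimated correlation), the NAD-consuming enzymes (adjusted p = 0.0878 with an estimated correlation) and the melanocyte lineage (camera adjusted p = 0.00985, and adjusted p = 0.284 with an estimated correlation), where Mitf was the 1 called member of 16 and 8 fell with the block. With the block and an estimated correlation the chemokines (adjusted p = 0.00656) and the NAD-consuming enzymes (0.0458; list median -0.01, mean 0.54) passed, and the class II genes did not (0.0662). Of the checkpoint ligands 6 of 8 rose with the block. Of 14 immediate early genes Zfp36 rose by 2.04 (0.25) and Jun by 1.35 (0.25), and Fosb fell by 1.28 (0.27). In the other lists 2 of 25 ATF4 genes, 1 of 16 NRF2 genes and 1 of 16 hypoxia genes rose and 1 hypoxia gene fell (adjusted over the list alone 2, 2, 1 and 1), and no member was called in the rest, where adjusted over the list alone 1 fibroblast, endothelial and keratinocyte marker fell, Col1a2. With the block 6 NF-kB targets rose, 5 immediate early genes rose and 6 fell, 2 hypoxia genes rose and 7 fell, and 4 ATF4 genes rose and 3 fell. Also with the block 2 p53 targets rose and 4 fell, 2 NRF2 genes rose and 2 fell, 1 glycolysis gene rose and 3 fell, 5 cholesterol genes and 3 DNA replication genes fell, 2 NAD biosynthesis genes rose and 1 fell, and at most 1 rose or fell in each of the rest.

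Some of these calls were lost when 1 library was left out of the fit without the block, which breaks a pair. The block with all libraries kept them. That of Gjb2 was lost without media 3 or 5 or IFNγ plus FK866 3 or 4 (adjusted p = 0.0516, 0.077, 0.0705 and 0.0638), and that of Rab3a without media 4 or 5 or IFNγ plus FK866 3, 4 or 5 (0.0997, 0.099, 0.0892, 0.0627 and 0.0788). Zfp469 was lost without media 3, 4 or 5 or IFNγ plus FK866 4 or 5 (0.0979, 0.0529, 0.076, 0.0926 and 0.099), Stum without media 4 or IFNγ plus FK866 3 or 5 (0.0712, 0.0717 and 0.0788), and Jun without media 4 or 5 or IFNγ plus FK866 4 (0.0767, 0.079 and 0.0547). Fosb was lost without media 3 or 5, IFNγ 4 or 5 or IFNγ plus FK866 3, 4 or 5 (0.108, 0.0713, 0.0534, 0.0535, 0.104, 0.163 and 0.0745) and with only these 2 groups in the fit (0.083).

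In total 421 genes were higher and 91 lower with IFNγ plus FK866 than in media (326 and 28 by at least 2-fold; 1299 and 1160 with the replicate block). The number of lower genes was 198 with DESeq2, and 59 with only these 2 groups in the fit. It was 34, 42 and 58 without IFNγ plus FK866 libraries 4, 5 and 3, and 38, 43 and 53 without media libraries 4, 5 and 3. Both comparisons with media shared 396 higher and 61 lower genes, where independent lists would share 11.8 and 0.454. Simulated groups without any effect shared 0, and simulations without an FK866 effect shared 393 higher genes; 0 genes were called in opposite directions. The 61 shared lower genes became 35, 22 and 19 without media 3, 4 and 5, 22, 22 and 34 without IFNγ 3, 4 and 5, and 29 and 35 without IFNγ plus FK866 4 and 5. With the block 1089 higher and 779 lower genes were shared. Across genes, which are not independent replicates, the log2 fold changes correlated by 0.953, with a covariance of 0.637. Simulations without any effect gave 0.495 and 0.0255. Those without an FK866 effect gave 0.963 (range 0.961 to 0.965) and 0.706 (0.682 to 0.725), so both observed values lay below the simulated range, and the cause was not tested. The media libraries are too few to be split. In the simulations without any effect, shared media libraries alone gave 0 shared calls and a covariance of 0.0255. These simulations called 0 genes in either comparison, so they cannot show what sharing adds to the overlap once genes respond. The covariance in them argues against shared media libraries as the source of most of the observed covariance. Shared media libraries do add to the correlation, which was 0.495 in those simulations.

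**Figure D4:**
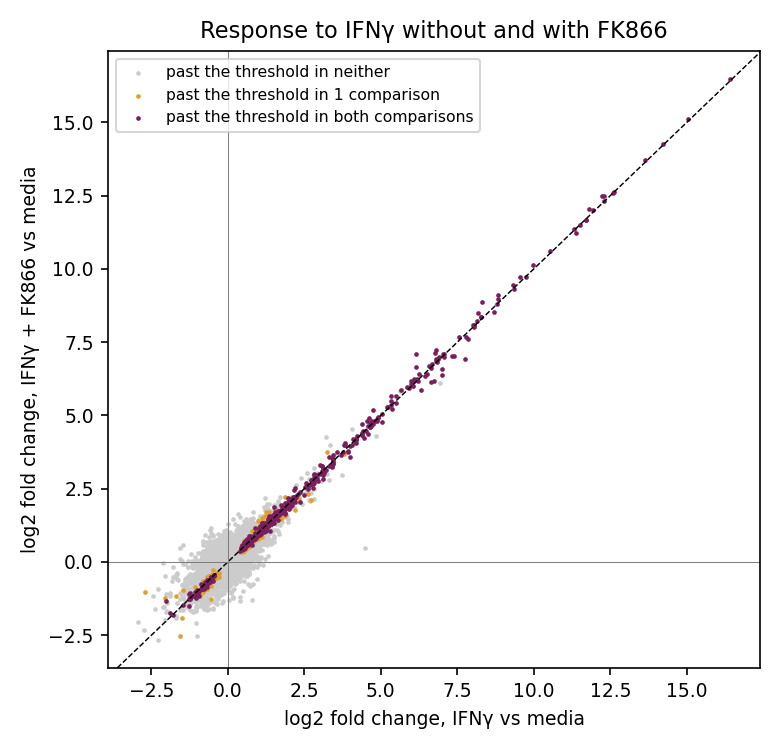
log2 fold change against media with IFNγ (x axis) and with IFNγ plus FK866 (y axis) for each of the 15237 genes tested; colours mark genes past the threshold in neither, 1 or both comparisons, and the dashed line marks equal values. The correlation across genes is 0.953, and the values at the upper right are fitted values of genes without counts in media, whose size depends on the prior count.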

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

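Alternatives chosen after the data were seen are those limited to protein-coding nuclear genes, those combining the block with other size factors, another tool or a left-out number, and the baseline limited to the same number. Of the named genes' values under other settings, 1977 kept their direction and side of the threshold, 66 lost a call, 35 gained one and 15 changed sign. When 1 library was left out of the fit without the block, 9 of 40 named calls were lost at least once for IFNγ against media. For IFNγ plus FK866 against media these were 6 of 23. Among the named genes, the block changed no call other than those given in the report and here.

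Over the 9 fits that leave out 1 library, IFNγ against media gave 287 to 420 higher and 26 to 68 lower genes, IFNγ plus FK866 against media 284 to 406 and 34 to 75, both together 266 to 374 and 19 to 49, and IFNγ plus FK866 against IFNγ 0 and 0. The share of induced genes lower with FK866 ran from 30.9% to 77.3% and their median from -0.122 to 0.093. Signs changed for Nampt (-0.18 to 0.03), Cd274 (-0.11 to 0.13), Cxcl10 (-0.62 to 0.47) and Cebpb (-0.06 to 0.33) between IFNγ plus FK866 and IFNγ, Cd74 (-0.23 to 1.22) with IFNγ against media, and Gm24497 (-0.66 to 0.48) and CT010467.1 (-0.32 to 0.09) with IFNγ plus FK866 against media; none of these had been called. Fewer libraries explain lower counts by construction. A broken pair in the fit without the block explains the shifts of Cxcl10 and Cd274, whose levels differ between numbers. Cd274 had 278.18, 290.11 and 217.31 CPM with IFNγ in 3, 4 and 5, and differences within pairs of -0.035, 0.052 and -0.002. The cause of the other sign changes was not tested.

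DESeq2 gave 180, 198 and 151 lower genes (IFNγ, IFNγ plus FK866, both), and only 2 groups in the fit gave 59 with IFNγ plus FK866. Library totals alone gave 37.6% and a median of 0.031 for the induced genes. The median of all genes tested moved with it, from -0.014 with TMM scaling to 0.023, so this shift is not particular to the induced genes. With another IFNγ library as baseline the medians were -0.051 (library 3), -0.116 with 71.5% lower (4) and 0.235 with 22.4% lower (5), and within the same number 45.5% (4) and 61.4% with a median of -0.042 (5). Lists past the threshold for IFNγ against media numbered 9, and 14 with fry; for IFNγ plus FK866 against IFNγ 3, 0 with an estimated correlation, 0 with fry, 7 with the block, and 2 with fry and the block (immediate early genes and NF-kB targets, adjusted p = 0.041 each). The cause of the other differences was not tested.

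In the order higher and lower for IFNγ against media, for IFNγ plus FK866 against media, and for both, the replicate block gave 1237, 936, 1299, 1160, 1089 and 779 genes; with protein-coding nuclear genes only 1113, 864, 1115, 1101, 981 and 741; with DESeq2-style size factors 1227, 937, 1309, 1129, 1090 and 772; with DESeq2 1079, 759, 1119, 906, 964 and 638; with limma-voom 1243, 907, 1292, 1164, 1095 and 779; without number 3 1100, 783, 1501, 1101, 981 and 662; without number 4 867, 535, 855, 543, 750 and 421; without number 5 1152, 678, 1188, 701, 1032 and 529. Between IFNγ plus FK866 and IFNγ the block gave 2 higher and 1 lower gene, 2 and 1 with other size factors, 1 higher with DESeq2, 2 and 1 with limma-voom, 5 and 3 without number 3 (46.8% of induced genes lower), 1 higher without number 4, and 2 and 1 without number 5; with protein-coding nuclear genes only it gave 0. Depth limits genes at a few counts, such as Vcam1 with 6 counts over the media group.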

Other observations

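All tests in this part were chosen after their result was seen except those of chromosome copy number and of hidden 2-fold changes. Libraries of different numbers differed in many genes regardless of treatment, with 7895 of 15237 genes (51.8%) past an adjusted p of 0.05 for the number in the edgeR fit with the block. Among genes with a mean CPM of at least 5, 87 differed at least 4-fold and 24 at least 16-fold. The genes named here were picked because they differ. Carmil2 had 461 ± 65.6 CPM in the libraries of number 3 (SD over the 3 treatments, n = 3), 2.80 ± 0.842 in number 4 and 2.12 ± 0.884 in number 5. Lgals3, which encodes galectin-3, had 0.0847 ± 0.0956, 71.8 ± 3.72 and 76.6 ± 8.99 CPM, and the cation channel gene Mcoln3 67.6 ± 6.47, 0.193 ± 0.168 and 33.2 ± 4.98 CPM. Most members of many lists differed, such as 20 of 20 for cholesterol biosynthesis, 16 of 16 for NRF2 and redox, 35 of 36 for nuclear OXPHOS subunits and 14 of 16 for the melanocyte lineage, which did not stand out. Of the latter list, Tyr, the rate-limiting enzyme of pigment synthesis, had 202 ± 32.1, 113 ± 23.6 and 393 ± 61.1 CPM. The receptor gene Met had 134 ± 28.9, 358 ± 109 and 741 ± 165 CPM.

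The difference between the IFNγ libraries and the media library of the same number is given here as values without a test, since each number has 1 media library. Over the 325 genes induced at least 2-fold, the medians were 2.4, 2.42 and 2.19 on the log2 scale in numbers 3, 4 and 5. Of these genes 155 were lower in number 5 than in both others. The type I IFN and antiviral genes had medians of 3.64, 3.39 and 2.91. The JAK-STAT and IRF regulators went the other way, with 3.15, 3.08 and 3.48. Some genes, picked because they differ, lay further apart. For B2m the mean of both IFNγ groups lay 1.36, 1.34 and 0.36 above media, for Tap1, a subunit of the peptide transporter of MHC class I loading, 5.09, 7.15 and 8.07, and for Parp12 3.59, 3.19 and 2.41.

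The genes high in 1 number and near 0 in another may come from sublines of the cells. Levels are scaled to library totals, and the mean totals of the numbers differed by a factor of 1.06, which argues against sequencing depth. Markers of leukocytes, fibroblasts, endothelial cells and keratinocytes reached at most 11.7 CPM, scaled by library totals, in any library, which argues against those cells. At these low levels Cd68 (7.65, 10.1 and 3.66 CPM in numbers 3, 4 and 5) and Pdgfra (1.11, 6.72 and 1.89) differed between numbers. Markers of further cell types were not examined. A difference in chromosome copy number is a candidate explanation for part of it: the median of chromosome 14 (345 genes) was higher in number 3 than in numbers 4 and 5 by at least 0.356 on the log2 scale in every treatment, and that of chromosome 7 (711 genes) was lower by -0.321 and -0.32 or more, where the highest value of 100 shuffles was 0.067. Most genes near 0 need more than a copy number change, and no test here reads DNA. The titles name Control 3, 4 and 5 without saying what these are. The labels name no subline, so no biological explanation from the design was tested.

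Between IFNγ plus FK866 and IFNγ, 0 genes were called without the block, and 2 higher and 1 lower with it. A shared fall of the induced genes by 1.5-fold does not show, with a mean of the pair medians of -0.011 (SD 0.023), and for 0.617% of the 10377 genes with a mean CPM of at least 5 the blocked 95% interval reached a 2-fold change, which leaves those 64 genes open. Libraries exchanged within a pair cannot be told apart from correct labels, because exchanging 1 pair called 13, 2 or 22 genes in a blocked fit of the 6 libraries against 8 with the labels as given. An inactive or slow inhibitor, or a response that needs longer than 6 h, stays open, since no NAD level was measured in these libraries.

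The 10 splits of 6 libraries are too few for a share under 0.05. For IFNγ against media the labels called 418 genes and the highest other split 1, so that 1 of 10 called as many. For IFNγ plus FK866 against media the counts were 421 and 0, again 1 of 10. For IFNγ plus FK866 against IFNγ they were 0 and 1. There 10 of 10 called as many, which cannot decide anything, because every split calls at least 0. For the lists, 8 of 10 splits called at least the 9 of the labels for IFNγ against media (highest other 14), 6 of 10 at least 9 for IFNγ plus FK866 against media (13), and 7 of 10 at least 3 for IFNγ plus FK866 against IFNγ (15). In the comparisons with media, every other split sets 2 libraries of 1 treatment and 1 of the other against the rest. Such splits keep part of the IFNγ effect, so their list counts do not show what chance alone gives. Of the 4 splits that part every pair, the other 3 called 0 genes in each comparison and at most 9, 11 and 1 lists where the labels called 9, 9 and 3 (IFNγ with media, IFNγ plus FK866 with media, IFNγ plus FK866 with IFNγ), and with the block 0 genes against 2120 for IFNγ and 0 against 1918 for IFNγ plus FK866 with media. With the block these 3 splits called at most 8, 9 and 8 lists where the labels called 10, 9 and 7, in the same order. Against media these 3 splits also keep part of the IFNγ effect, so they cannot decide whether the list counts of the labels stand out. For IFNγ plus FK866 against IFNγ, the list count with the block does not stand out from these splits. In that comparison without the block, 3 lists against at most 1 goes the other way. The splits that call 15 and 14 lists put 2 libraries of 1 number on the same side, which points to the difference between numbers.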
